A study of Homo sapiens with 15 samples.

How the data were processed

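RNA was taken from cultured HEKa keratinocytes with the miRNeasy kit, per the labels' protocols, after 3 hours with bacteria or with media, and 1 library was made from each of 15 samples in 5 groups of 3. Groups and replicate numbers were taken from the sample titles. The deposited table holds whole-number counts of reads per gene. Per the submitters' processing notes, reads were aligned with STAR 2.4.2a to GRCh37 and counted with featureCounts of Subread 1.5.0. The annotation release, the use of strand and the handling of reads with several matches are not given in the sources used here, so counts of near-identical genes and of genes that overlap on the other strand are uncertain. Gene coordinates are those of the deposited table. Symbols were taken from a table of gene names and biotype and GC content from GENCODE release 29, which was used for nothing else, and 52338 of the 57905 gene IDs matched.

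The counts were used as deposited. Totals per library ran from 36077688 to 59794373, so that 5 CPM stands for over 100 reads in every library. Intervals given for genes with up to 3 counts in a group are exact 95% binomial intervals of the depth-scaled ratio and, since no molecular identifiers are given, cover counting error only. Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersions and TMM factors, on the 18133 genes kept by the filterByExpr function. All 15 libraries entered 1 model of the group means, which share 1 estimate of the spread because each group has 3 libraries. The 10 comparisons were each bacterium with media, each anaerobe with S. epidermidis and the anaerobes with one another, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The SE of a log2 fold change is its size divided by the square root of F. CPM values use the TMM-scaled library sizes.

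Gene lists for 32 pathways, families and cell types were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and all alternatives except those on GC content and on libraries that stood apart. Their 573 matched genes include none for CCL3, CCL4, CCL5, DUSP14, MMP12, MMP28 and PECAM1, which are not analysed here. The entry S100A15, an older name of S100A7A, added no further gene. Lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over the 32 lists of a comparison. The named genes were the 8 largest rises and 6 largest falls against media, and the 5 largest of each between bacteria. They had to be called, protein-coding, at a mean of 5 CPM or more and without overlap between the groups, which chance alone gives for 10% of genes. From each list up to 4 called members were added by the size of their change, and for a list without a call its 2 members with the highest CPM. Genes named for several bacteria at once were taken from these, and some genes that the rule takes are not reported here.

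The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, total-count scaling, no filter on low counts, a test against a fold change of 1.5, only the 2 groups compared in the fit, the replicate number in the model and each library left out in turn. After seeing the data, 4 were added: GC offsets, which remove a spline of each library's deviations from the mean over libraries on gene GC content with 5 degrees of freedom, a GC covariate, which is each library's slope on GC content as a term of the model, the fit without 4 of the 5 libraries that stood apart from their group on the GC axis (P. nigrescens 3, P. melaninogenica 1, S. epidermidis 3 and media 3), and the fit without all 5, F. nucleatum 3 included. Overlaps between comparisons with shared libraries were set beside independent lists and 20 simulations of unchanged groups.

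Tests were tried on simulated counts with 50 genes changed by each of 1.5, 2, 4 and 8-fold, fewer than were called. For P. nigrescens against media (16963 genes), edgeR recovered 12, 38, 49 and 50 of 50, and 5.10% of calls were unchanged genes. For F. nucleatum against media (16960 genes) it recovered 6, 37, 49 and 50, and 5.96% of calls were unchanged genes (15.5% with DESeq2). Camera called 0 of 20 unchanged lists for P. nigrescens. Correlation between genes was not simulated, so it is not covered. Every pair of libraries of a group differed beyond sampling noise, so each library was 1 sample. Chi-square per degree of freedom was 4.97 to 129 over genes with at least 20 reads in the pair.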

Results

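Messenger RNA levels were measured by RNA sequencing in HEKa cells, which are normal epidermal keratinocytes from adult human skin grown in culture. The cells were kept for 3 hours with 2000000000 bacteria per ml of Prevotella nigrescens, Fusobacterium nucleatum, Prevotella melaninogenica or Staphylococcus epidermidis, or with media and no bacteria. The first 3 of these are Gram-negative anaerobes, and S. epidermidis is a Gram-positive bacterium common on skin. The series set out to compare the gene signatures that the anaerobes induce. The media libraries served as the untreated background. Nothing in the labels says whether the 3 libraries of a group came from separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical. Of 57905 genes, 18133 had enough counts to be tested. Levels are given in CPM, the counts scaled to library size, as mean ± SD with n = 3, and log2 fold changes with their SE. Adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested. For the gene lists, a count adjusted over the list alone is given where it differs from that over all genes tested, and a p with an estimated correlation where it ends the call of the camera test. A list median with total-count scaling differs by the shift of all genes, which does not bear on the list against other genes. GC offsets also shift all genes, since they change the scaling of each library.

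Along the first principal component, which held 45.0% of the variance, media lay at one end, F. nucleatum at the other and S. epidermidis nearer to media, and the 2 Prevotella groups overlapped. The second component held 24.3% and followed GC content: across genes, its loadings had a Spearman correlation of -0.66 with the GC content of the longest transcript, genes being no independent replicates. Within each of the 5 groups, 1 library stood apart from the other 2 on this axis. The slope of log2 CPM on GC, per 10 points of GC, was 0.0031 in P. nigrescens replicate 3 against -0.33 and -0.25 in the others of its group. It was 0.38 in P. melaninogenica replicate 1, 0.43 in S. epidermidis replicate 3 and -0.30 in media replicate 3, and the other libraries of these groups lay between -0.089 and 0.054. In F. nucleatum replicate 3 it was -0.10 against 0.11 and 0.16. Group means of this slope were -0.10 ± 0.18 in media, -0.19 ± 0.17 with P. nigrescens, 0.058 ± 0.14 with F. nucleatum, 0.10 ± 0.24 with P. melaninogenica and 0.13 ± 0.27 with S. epidermidis (SD, n = 3). The share of counts on mitochondrially encoded genes was 4.35 ± 0.188% with F. nucleatum and 5.72 ± 0.199% in media, with 5.79 ± 0.143%, 5.93 ± 0.294% and 5.88 ± 0.0865% for P. nigrescens, P. melaninogenica and S. epidermidis.

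**Figure D1:**
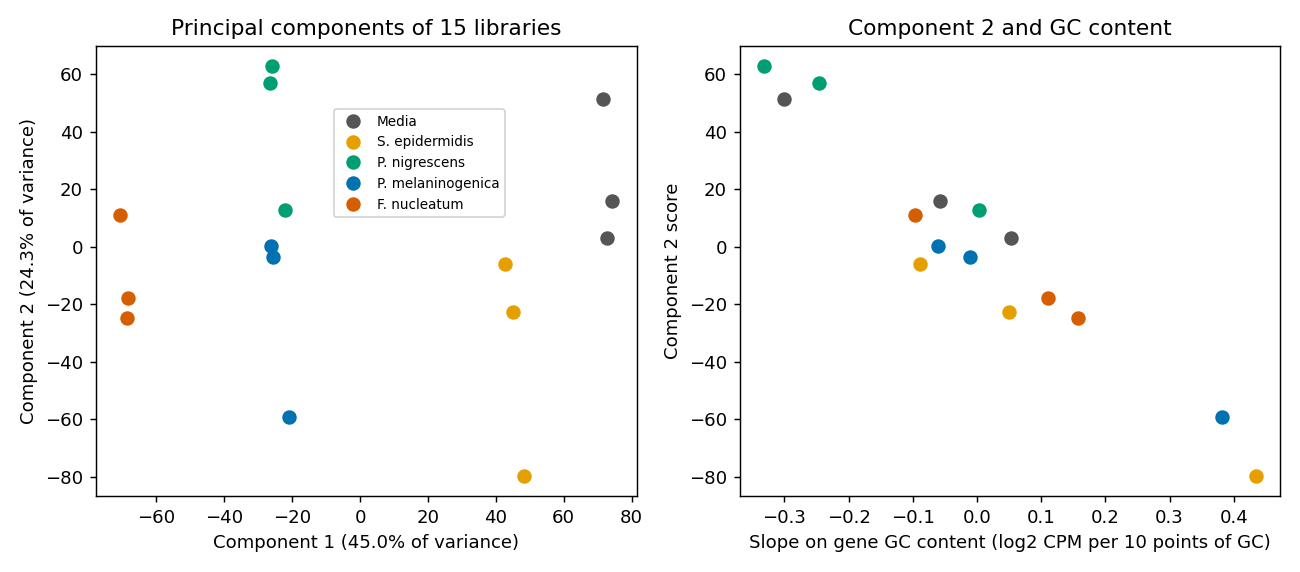
Principal component scores of the 15 libraries (left, component 1 against component 2, in units of the component) and the score on component 2 against the slope of log2 CPM on gene GC content per 10 points of GC (right), with 1 point per library coloured by group. Media, S. epidermidis and F. nucleatum lie apart along component 1 while the 2 Prevotella groups overlap, and the libraries with slopes of 0.43 and 0.38 lie at the low end of component 2.

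F. nucleatum against media. The comparison asked which keratinocyte genes changed within 3 hours of contact with this anaerobe. Among the largest rises were genes of inflammation. CXCL8 (ENSG00000169429, chromosome 4, 74606223 to 74609433 of GRCh37), a chemokine that attracts neutrophils, rose from 6.69 ± 0.982 to 4779 ± 140.0 CPM, a log2 fold change of 9.48 ± 0.18 (adjusted p = 2.4e-13). CCL20 (ENSG00000115009, chromosome 2, 228678558 to 228682272), a chemokine for cells with the receptor CCR6, rose from 0.543 ± 0.136 to 887 ± 4.31 CPM, and IL36G (ENSG00000136688, chromosome 2, 113730780 to 113743242), an epidermal cytokine, from 3.15 ± 0.837 to 1492 ± 40.3 CPM. The interleukin gene IL6 rose from 1.77 ± 0.241 to 1201 ± 138 CPM and CSF3, which encodes a growth factor for granulocytes, from 2.55 ± 0.518 to 530.4 ± 72.9 CPM (adjusted p at most 7.1e-10 for these 4 genes). Further genes with the largest rises were FGF19 at 143 ± 16.5 CPM with a log2 fold change of 10.96 ± 0.25, NPR1, a natriuretic peptide receptor, with 9.58 ± 0.21, and C2CD4A with 10.05 ± 0.25. BCL2A1, a relative of BCL2, had 1 count over the 3 media libraries and 3806 over the 3 exposed ones, a depth-scaled ratio of 5210 with a 95% counting interval of 935 to 205900. Its fitted log2 fold change was 11.80, and 11.20 without media replicate 1 and 13.42 without media replicate 3. TNFAIP6 had 2 counts over the 3 media libraries and 2702 over the 3 exposed ones, a depth-scaled ratio of 1850 with a 95% counting interval of 512 to 15280. Among 7 neutrophil chemokines, 6 rose and 0 fell, and the median log2 fold change was 6.05 (camera adjusted p = 3.7e-10). Reads can be shared between CXCL1, CXCL2 and CXCL3, so the values of each are uncertain. 29 cytokines were tested, and 25 rose and 0 fell (25 and 1 adjusted over the list alone) (median log2 fold change 4.72, camera adjusted p = 7.6e-20). Other chemokines had 9 tested members, of which 7 rose and 1 fell (median log2 fold change 2.77, camera adjusted p = 3.0e-04). For NF-kB feedback and target genes, 26 rose and 0 fell out of 26 (median log2 fold change 3.39, camera adjusted p = 2.9e-23). Among these TNFAIP2 rose from 3.02 ± 0.812 to 3511 ± 370.2 CPM, ICAM1, an adhesion molecule for leukocytes, from 11.5 ± 1.08 to 1530 ± 147 CPM, and TRAF1 from 3.02 ± 0.225 to 395 ± 38.2 CPM.

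Growth factor, early response and tissue remodelling genes rose with F. nucleatum as well. The immediate early and AP-1 genes moved by a median log2 fold change of 2.12, and 22 rose and 1 fell of 24 (camera adjusted p = 2.5e-16). The orphan nuclear receptor genes NR4A3 and NR4A1 rose from 0.143 ± 0.0971 to 76.3 ± 1.08 CPM and from 0.512 ± 0.0481 to 75.8 ± 8.39 CPM, and ATF3 from 7.77 ± 1.34 to 339.7 ± 25.2 CPM. The log2 fold change of NR4A3 was 9.02, and 9.65 without media replicate 3. Of the 8 tested EGFR ligands, 7 rose and 0 fell, with a median log2 fold change of 1.57 (camera adjusted p = 3.1e-06). EREG rose from 62.1 ± 9.68 to 3251 ± 331 CPM and HBEGF from 43.4 ± 4.43 to 738 ± 54.0 CPM. Among 16 ERK feedback phosphatases and sprouty genes, 10 rose and 4 fell, and the median log2 fold change was 1.12 (camera adjusted p = 0.0013, and adjusted p = 0.22 with an estimated correlation). In this group DUSP1 rose by 4.54 ± 0.17 log2, while SPRY1 fell by 3.84 ± 0.40 log2. Its value was -3.84, and -4.43 without F. nucleatum replicate 2. 22 matrix proteases and inhibitors were tested, and 19 rose and 1 fell (20 and 1 adjusted over the list alone) (median log2 fold change 2.58, camera adjusted p = 1.2e-13). Those that rose included ADAMTS4 (from 0.986 ± 0.177 to 115 ± 8.74 CPM), the urokinase receptor gene PLAUR (from 21.8 ± 3.54 to 1342 ± 143 CPM) and the collagenase gene MMP13 (from 0.967 ± 0.135 to 43.6 ± 7.61 CPM). Antimicrobial proteins had 16 tested members, of which 14 rose and 0 fell (16 and 0 adjusted over the list alone) (median log2 fold change 1.04, camera adjusted p = 4.9e-07, and adjusted p = 0.13 with an estimated correlation). PGLYRP4, a peptidoglycan recognition protein, rose from 3.54 ± 0.273 to 51.1 ± 0.345 CPM. For keratinocyte differentiation genes, 21 rose and 0 fell out of 31 (median log2 fold change 0.99, camera adjusted p = 2.5e-09, and adjusted p = 0.12 with an estimated correlation). The transcription factor genes OVOL1 and GRHL3 rose from 3.30 ± 0.366 to 146 ± 14.8 CPM and from 11.7 ± 0.299 to 244 ± 2.98 CPM, and SPRR2A, of a family of cornified envelope proteins with near-identical members whose reads can be shared, from 14.5 ± 2.17 to 391 ± 26.4 CPM. The wound-induced keratins moved by a median log2 fold change of 0.68, and 4 rose and 0 fell (5 and 0 adjusted over the list alone) of 5 (camera adjusted p = 0.0053, and adjusted p = 0.25 with an estimated correlation). KRT6B rose from 1266 ± 127 to 5353 ± 497 CPM, with reads that can be shared among KRT6A, KRT6B and KRT6C.

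Stress and metabolic genes moved in both directions. Of the 23 tested unfolded protein response genes, 17 rose and 0 fell, with a median log2 fold change of 0.50 (camera adjusted p = 2.3e-06, and adjusted p = 0.12 with an estimated correlation). HERPUD1, a component of protein degradation at the endoplasmic reticulum, rose from 255 ± 78.1 to 1172 ± 103 CPM and the chaperone gene HSPA5 from 2039 ± 229.8 to 5296 ± 106 CPM. Among 27 genes of the integrated stress response and amino acid deprivation, 15 rose and 0 fell (18 and 0 adjusted over the list alone), and the median log2 fold change was 0.51 (camera adjusted p = 6.6e-05, and adjusted p = 0.25 with an estimated correlation). CHAC1 rose from 19.7 ± 6.30 to 77.2 ± 9.48 CPM and DDIT3 from 21.3 ± 6.11 to 69.1 ± 8.70 CPM. 24 NRF2 oxidative stress genes were tested, and 12 rose and 0 fell (median log2 fold change 0.34, or -0.011 with total-count scaling, camera adjusted p = 1.2e-04, and adjusted p = 0.19 with an estimated correlation). TXNRD1, thioredoxin reductase, rose from 144 ± 5.03 to 1050 ± 72.3 CPM. Metallothioneins had 8 tested members, of which 8 rose and 0 fell (median log2 fold change 1.14, camera adjusted p = 0.0012, and adjusted p = 0.16 with an estimated correlation). For aryl hydrocarbon receptor targets, 7 rose and 0 fell out of 9 (median log2 fold change 1.42, camera adjusted p = 1.1e-04). CYP1A1 (ENSG00000140465, chromosome 15, 75011883 to 75017951), a cytochrome P450, rose from 17.3 ± 1.79 to 339.6 ± 24.3 CPM and CYP1B1 from 5.46 ± 2.28 to 106 ± 15.1 CPM. The hypoxia response genes moved by a median log2 fold change of 0.29, or -0.065 with total-count scaling, and 12 rose and 3 fell (13 and 3 adjusted over the list alone) of 27 (camera adjusted p = 0.0051, and adjusted p = 0.16 with an estimated correlation). NDRG1 rose from 253 ± 29.03 to 1860 ± 149 CPM. Of the 23 tested genes of cholesterol synthesis and uptake, 0 rose and 9 fell, with a median log2 fold change of -0.29 (camera adjusted p = 0.0012, and adjusted p = 0.12 with an estimated correlation). HMGCS1 (ENSG00000112972, chromosome 5, 43289497 to 43313614) fell from 393 ± 45.3 to 166 ± 26.5 CPM (adjusted p = 6.0e-04). Among 25 mitotic cell cycle genes, 0 rose and 19 fell (0 and 21 adjusted over the list alone), and the median log2 fold change was -1.15 (camera adjusted p = 4.7e-09). The mitotic kinase gene AURKA (ENSG00000087586, chromosome 20, 54944445 to 54967393) fell from 49.5 ± 3.00 to 11.5 ± 0.838 CPM, and HJURP, a chaperone of centromere chromatin, from 29.1 ± 1.04 to 3.52 ± 0.310 CPM. 25 type I interferon response genes were tested, and 1 rose and 12 fell (1 and 14 adjusted over the list alone) (median log2 fold change -0.54, camera adjusted p = 0.0047, and adjusted p = 0.27 with an estimated correlation). IFIT1 fell from 153 ± 14.5 to 27.5 ± 4.21 CPM and IFIT3 from 102 ± 21.1 to 24.4 ± 2.35 CPM, while ISG20 rose from 3.80 ± 0.601 to 73.9 ± 9.03 CPM. The transcriptional repressor gene SNAI2 fell from 190.2 ± 7.65 to 25.4 ± 1.26 CPM. Mitochondrially encoded genes had 13 tested members, of which 0 rose and 7 fell (0 and 8 adjusted over the list alone) (median log2 fold change -0.28, camera adjusted p = 7.3e-04, and adjusted p = 0.25 with an estimated correlation).

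Lists that did not pass the camera test with F. nucleatum were as follows. For receptors and cell death genes they were pattern recognition receptors and adaptors (7 up and 2 down of 20, 8 and 4 adjusted over the list alone, median log2 fold change 0.21, or -0.14 with total-count scaling and -0.034 with GC offsets, adjusted p = 0.13) and inflammasome and pyroptosis genes (4 up and 0 down of 13, 4 and 0 adjusted over the list alone, median log2 fold change 0.14, or -0.22 with total-count scaling, adjusted p = 0.19). For lipid mediators and structural genes they were prostaglandin synthesis (3 up and 1 down of 12, 3 and 1 adjusted over the list alone, median log2 fold change 0.16, or -0.19 with total-count scaling and -0.046 with GC offsets, adjusted p = 0.17) and basal keratinocyte genes (6 up and 1 down of 17, 6 and 1 adjusted over the list alone, median log2 fold change 0.17, or -0.19 with total-count scaling, adjusted p = 0.19). The other 3 were heat shock genes (8 up and 2 down of 20, 8 and 2 adjusted over the list alone, median log2 fold change 0.22, or -0.14 with total-count scaling, adjusted p = 0.061), p53 targets (8 up and 4 down of 19, 9 and 4 adjusted over the list alone, median log2 fold change 0.017, or -0.34 with total-count scaling and -0.24 with GC offsets and -0.039 with a GC covariate, adjusted p = 0.19) and TGF-beta targets (4 up and 5 down of 15, 5 and 5 adjusted over the list alone, median log2 fold change 0.046, or -0.31 with total-count scaling and -0.22 with GC offsets and -0.052 with a GC covariate, adjusted p = 0.91). Named members of these included NOD2, a sensor of peptidoglycan fragments, which rose from 2.66 ± 0.296 to 32.8 ± 2.24 CPM, PTGS2, the inducible cyclooxygenase, which rose from 155 ± 25.1 to 1367 ± 178 CPM, and BBC3, which rose from 3.71 ± 1.12 to 23.01 ± 3.60 CPM. Markers of other cell types were also counted. For endothelial markers, 2 rose and 0 fell (3 and 0 adjusted over the list alone) out of 4 (median log2 fold change 3.82 (3.68 with members of up to 3 counts set at 3 counts), camera adjusted p = 0.029, and adjusted p = 0.12 with an estimated correlation). CDH5 stood at 9.63 ± 0.486 CPM against 0.0245 ± 0.00511 CPM in media. The fibroblast markers had a median log2 fold change of -0.014, or 0.0067 with DESeq2 size factors and 0.0059 with a GC covariate, and the mean was 0.82, of the other sign and the test pointed up, against the median, and 3 rose and 1 fell of 8 (camera adjusted p = 0.66). LUM rose from 0.177 ± 0.0515 to 9.24 ± 1.46 CPM. The melanocyte and the leukocyte and Langerhans cell markers had 4 and 3 tested members and 0 calls in either (camera adjusted p = 0.91 and 0.66, edgeR).

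In total 7058 genes differed between F. nucleatum and media in edgeR's quasi-likelihood test, 3767 higher and 3291 lower, and 3342 of them changed by 2-fold or more (2231 higher and 1111 lower). For F. nucleatum, the calls were 2548 higher and 7520 lower with total-count scaling (median of all tested genes -0.38) and 3673 higher and 6378 lower with GC offsets (median of all tested genes -0.17). Beside the 7058 calls, a GC covariate gave 11237 calls and a test against a fold change of 1.5 gave 3178.

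**Figure D2:**
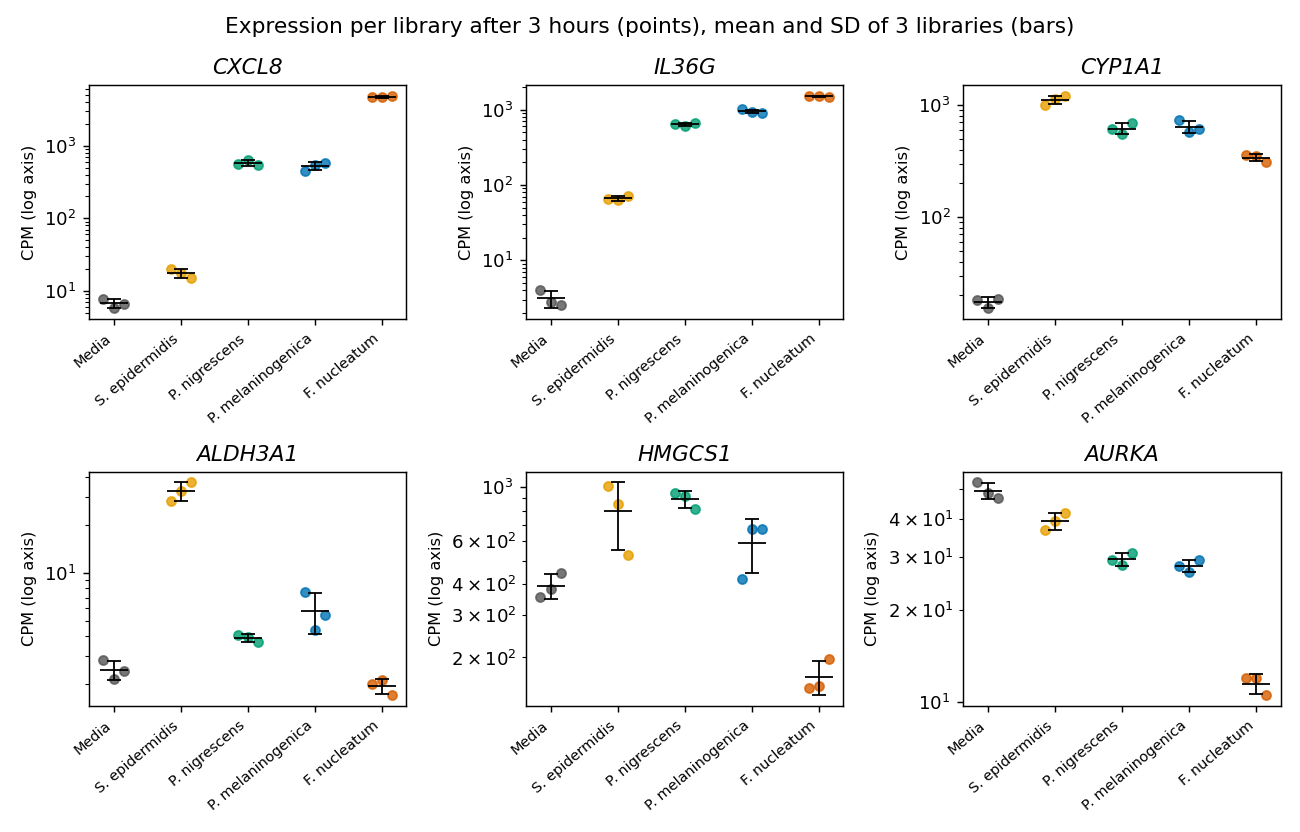
Expression of 6 genes in CPM (log axis) by group, with 1 point per library and bars for the mean and SD of 3 libraries. CXCL8 ran from 6.69 CPM in media to 4779 CPM with F. nucleatum, CYP1A1 was highest with S. epidermidis at 1114 CPM, and HMGCS1 was lowest with F. nucleatum at 166 CPM.

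P. nigrescens against media. The same inflammatory genes were followed with this anaerobe. CXCL8 rose from 6.69 ± 0.982 to 584 ± 49.5 CPM (log2 fold change 6.44 ± 0.16, adjusted p = 7.6e-12), IL36G from 3.15 ± 0.837 to 640.1 ± 30.6 CPM and CCL20 from 0.543 ± 0.136 to 76.8 ± 0.705 CPM. IL6 rose from 1.77 ± 0.241 to 110.1 ± 10.9 CPM, and IL16, a chemoattractant for CD4 cells, from 0.456 ± 0.108 to 18.5 ± 2.68 CPM. The protease gene ADAMTS9 rose from 0.296 ± 0.1001 to 34.5 ± 3.44 CPM (adjusted p at most 4.2e-10 for these 5 genes). Of the 7 tested neutrophil chemokines, 6 rose and 0 fell, with a median log2 fold change of 3.86 (camera adjusted p = 1.7e-09). Among 29 cytokines, 22 rose and 0 fell (23 and 0 adjusted over the list alone), and the median log2 fold change was 1.69 (camera adjusted p = 5.1e-15). 26 NF-kB feedback and target genes were tested, and 23 rose and 0 fell (26 and 0 adjusted over the list alone) (median log2 fold change 2.01, camera adjusted p = 1.1e-19). TNFAIP2 rose from 3.02 ± 0.812 to 295 ± 23.1 CPM and ICAM1 from 11.5 ± 1.08 to 165 ± 13.7 CPM. Immediate early and AP-1 genes had 24 tested members, of which 19 rose and 1 fell (21 and 1 adjusted over the list alone) (median log2 fold change 1.12, camera adjusted p = 8.4e-12, and adjusted p = 0.052 with an estimated correlation). ATF3 rose from 7.77 ± 1.34 to 187 ± 16.9 CPM. For EGFR ligands, 5 rose and 1 fell out of 8 (median log2 fold change 0.96, camera adjusted p = 0.0089, and adjusted p = 0.052 with an estimated correlation). EREG rose from 62.1 ± 9.68 to 1232 ± 159 CPM. The matrix proteases and inhibitors moved by a median log2 fold change of 0.89, and 12 rose and 2 fell (14 and 2 adjusted over the list alone) of 22 (camera adjusted p = 4.5e-06, and adjusted p = 0.11 with an estimated correlation). PLAUR rose from 21.8 ± 3.54 to 805 ± 82.1 CPM and SERPINB2, an inhibitor of plasminogen activators, from 284 ± 14.97 to 2604 ± 93.4 CPM. Of the 16 tested antimicrobial proteins, 9 rose and 0 fell (12 and 0 adjusted over the list alone), with a median log2 fold change of 0.56 (camera adjusted p = 1.3e-04, and adjusted p = 0.30 with an estimated correlation). Among 31 keratinocyte differentiation genes, 15 rose and 0 fell (16 and 0 adjusted over the list alone), and the median log2 fold change was 0.70 (camera adjusted p = 1.0e-08, and adjusted p = 0.15 with an estimated correlation). OVOL1 rose from 3.30 ± 0.366 to 92.4 ± 13.8 CPM and ZNF750 from 2.605 ± 0.373 to 30.1 ± 1.01 CPM.

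Other groups moved in both directions with P. nigrescens. DUSP6, a phosphatase that limits ERK signalling, fell from 281 ± 18.4 to 48.4 ± 4.68 CPM, SNAI2 from 190.2 ± 7.65 to 39.6 ± 1.06 CPM and TP63, a transcription factor of basal keratinocytes, from 268 ± 19.0 to 98.9 ± 3.32 CPM (adjusted p at most 2.8e-07). CCDC8 and NUAK1 were among the largest falls, with log2 fold changes of -2.85 ± 0.15 and -2.29 ± 0.11. 8 metallothioneins were tested, and 0 rose and 3 fell (median log2 fold change -0.71, camera adjusted p = 0.022, and adjusted p = 0.38 with an estimated correlation). Genes of the integrated stress response and amino acid deprivation had 27 tested members, of which 0 rose and 6 fell (median log2 fold change -0.22, camera adjusted p = 0.034, and adjusted p = 0.69 with an estimated correlation, with 0.068 with GC offsets and 0.12 without P. nigrescens replicate 1 and 0.059 without P. nigrescens replicate 2 and 0.12 without media replicate 1 and 0.063 without media replicate 2). DDIT3 fell from 21.3 ± 6.11 to 7.21 ± 1.14 CPM, and HERPUD1 of the unfolded protein response from 255 ± 78.1 to 113 ± 4.96 CPM. For mitotic cell cycle genes, 0 rose and 12 fell out of 25 (median log2 fold change -0.43, camera adjusted p = 4.6e-04, and adjusted p = 0.052 with an estimated correlation). AURKA fell from 49.5 ± 3.00 to 29.4 ± 1.38 CPM. The type I interferon response genes moved by a median log2 fold change of -0.35, and 1 rose and 6 fell of 25 (camera adjusted p = 0.022, and adjusted p = 0.53 with an estimated correlation, with 0.18 without P. nigrescens replicate 3 and 0.058 without media replicate 2). Of the 9 tested aryl hydrocarbon receptor targets, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median log2 fold change of 1.35 (camera adjusted p = 3.9e-06). CYP1A1 rose from 17.3 ± 1.79 to 617 ± 71.2 CPM. Among 23 genes of cholesterol synthesis and uptake, 8 rose and 0 fell, and the median log2 fold change was 0.14, or -0.018 with total-count scaling (camera adjusted p = 0.018, and adjusted p = 0.30 with an estimated correlation, with 0.063 without P. nigrescens replicate 3 and 0.058 without media replicate 3). INSIG1, a regulator of sterol sensing, rose from 112 ± 5.39 to 288 ± 3.34 CPM. KDR, an endothelial marker, had 2 counts over the 3 media libraries and 215 over the 3 exposed ones, a depth-scaled ratio of 142 with a 95% counting interval of 38.8 to 1179.

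In edgeR's test 5690 genes differed between P. nigrescens and media, 3030 higher and 2660 lower, with 2428 at 2-fold or more (1717 higher and 711 lower). For P. nigrescens, the calls were 2345 higher and 4846 lower with total-count scaling (median of all tested genes -0.17) and 3298 higher and 5189 lower with GC offsets (median of all tested genes -0.11). Beside the 5690 calls, a GC covariate gave 10376 calls (5084 higher, 5292 lower) and a test against a fold change of 1.5 gave 2122. Without 4 of the libraries that stood apart on the GC axis the count was 9816, in a comparison of 2 libraries with 2, and 10983 without all 5.

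P. melaninogenica against media. With this anaerobe CXCL8 rose from 6.69 ± 0.982 to 526 ± 64.8 CPM (log2 fold change 6.29 ± 0.16, adjusted p = 5.6e-12), CCL20 from 0.543 ± 0.136 to 207 ± 26.1 CPM, IL36G from 3.15 ± 0.837 to 945 ± 52.8 CPM and TNFAIP2 from 3.02 ± 0.812 to 873 ± 136 CPM. FGF19 rose from 0.0715 ± 0.0216 to 46.7 ± 6.27 CPM and NPR1 from 0.129 ± 0.0535 to 46.4 ± 4.59 CPM (adjusted p at most 9.1e-12 for these 5 genes). 7 neutrophil chemokines were tested, and 6 rose and 0 fell (7 and 0 adjusted over the list alone) (median log2 fold change 4.06, camera adjusted p = 1.4e-11). Cytokines had 29 tested members, of which 23 rose and 0 fell (median log2 fold change 2.54, camera adjusted p = 7.4e-18). IL6 rose from 1.77 ± 0.241 to 116 ± 11.7 CPM. For NF-kB feedback and target genes, 24 rose and 0 fell (25 and 0 adjusted over the list alone) out of 26 (median log2 fold change 2.37, camera adjusted p = 4.0e-24). ICAM1 rose from 11.5 ± 1.08 to 452 ± 68.1 CPM. The other chemokines moved by a median log2 fold change of 2.35, and 6 rose and 0 fell (6 and 2 adjusted over the list alone) of 9 (camera adjusted p = 2.3e-04). CXCL10, an interferon-inducible chemokine, rose from 5.45 ± 2.30 to 122 ± 27.5 CPM. Of the 24 tested immediate early and AP-1 genes, 22 rose and 1 fell, with a median log2 fold change of 1.55 (camera adjusted p = 2.0e-17). Among 22 matrix proteases and inhibitors, 16 rose and 2 fell (17 and 2 adjusted over the list alone), and the median log2 fold change was 1.246 (camera adjusted p = 6.1e-10). PLAUR rose from 21.8 ± 3.54 to 1119 ± 161 CPM. 31 keratinocyte differentiation genes were tested, and 10 rose and 4 fell (11 and 5 adjusted over the list alone) (median log2 fold change 0.20, or -0.076 with total-count scaling, camera adjusted p = 0.0017, and adjusted p = 0.38 with an estimated correlation). GRHL3 rose from 11.7 ± 0.299 to 285 ± 28.8 CPM and SPRR2A from 14.5 ± 2.17 to 282 ± 41.0 CPM. Wound-induced keratins had 5 tested members, of which 5 rose and 0 fell (median log2 fold change 0.84, camera adjusted p = 7.0e-04, and adjusted p = 0.24 with an estimated correlation).

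Among stress genes, HMOX1, heme oxygenase, rose from 6.29 ± 0.427 to 24.5 ± 4.58 CPM and TXNRD1 from 144 ± 5.03 to 472 ± 69.5 CPM with P. melaninogenica. For NRF2 oxidative stress genes, 13 rose and 2 fell (16 and 2 adjusted over the list alone) out of 24 (median log2 fold change 0.57, camera adjusted p = 1.4e-05, and adjusted p = 0.18 with an estimated correlation). The unfolded protein response genes moved by a median log2 fold change of 0.33, and 12 rose and 0 fell (13 and 0 adjusted over the list alone) of 23 (camera adjusted p = 7.4e-04, and adjusted p = 0.24 with an estimated correlation). HERPUD1 rose from 255 ± 78.1 to 472 ± 40.1 CPM. Of the 9 tested aryl hydrocarbon receptor targets, 7 rose and 0 fell, with a median log2 fold change of 1.22 (camera adjusted p = 3.6e-06). CYP1A1 rose from 17.3 ± 1.79 to 639 ± 82.1 CPM and CYP1B1 from 5.46 ± 2.28 to 172 ± 45.7 CPM. Among 23 genes of cholesterol synthesis and uptake, 7 rose and 0 fell (10 and 0 adjusted over the list alone), and the median log2 fold change was 0.30 (camera adjusted p = 0.0048, and adjusted p = 0.18 with an estimated correlation). 25 mitotic cell cycle genes were tested, and 0 rose and 14 fell (1 and 20 adjusted over the list alone) (median log2 fold change -0.82, camera adjusted p = 1.6e-06). BUB1B, of the spindle checkpoint, fell from 25.9 ± 4.66 to 9.57 ± 2.55 CPM. Type I interferon response genes had 25 tested members, of which 1 rose and 8 fell (1 and 9 adjusted over the list alone) (median log2 fold change -0.36, camera adjusted p = 0.033, and adjusted p = 0.49 with an estimated correlation, with 0.060 without P. melaninogenica replicate 1 and 0.089 without media replicate 2). IFIT1 fell from 153 ± 14.5 to 48.6 ± 6.31 CPM. The kinase gene NUAK1 fell from 99.99 ± 4.78 to 18.4 ± 1.39 CPM, the ephrin receptor gene EPHA4 from 21.1 ± 1.54 to 4.26 ± 0.535 CPM and CCN2, a connective tissue growth factor, from 116 ± 12.3 to 38.3 ± 2.23 CPM (adjusted p at most 6.8e-07). For mitochondrially encoded genes, 11 rose and 0 fell (13 and 0 adjusted over the list alone) out of 13 (median log2 fold change 0.34, camera adjusted p = 5.2e-05, and adjusted p = 0.24 with an estimated correlation). CDH5, an endothelial marker, stood at 1.43 ± 0.104 CPM.

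With P. melaninogenica, 5656 genes differed from media in edgeR's test, 3048 higher and 2608 lower, of which 2252 changed by 2-fold or more (1346 higher and 906 lower). For P. melaninogenica, the calls were 1871 higher and 5876 lower with total-count scaling (median of all tested genes -0.32) and 3307 higher and 4645 lower with GC offsets (median of all tested genes -0.076). Beside the 5656 calls, a GC covariate gave 9813 calls (4812 higher, 5001 lower) and a test against a fold change of 1.5 gave 1842.

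S. epidermidis against media. Among the largest rises with this bacterium were 2 aryl hydrocarbon receptor targets, CYP1A1 and CYP1B1. CYP1A1 rose from 17.3 ± 1.79 to 1114 ± 99.8 CPM (log2 fold change 6.0 ± 0.15, adjusted p = 4.4e-11), CYP1B1 from 5.46 ± 2.28 to 245 ± 66.8 CPM, and ALDH3A1 (ENSG00000108602, chromosome 17, 19641297 to 19652256), an aldehyde dehydrogenase of the same list, from 2.46 ± 0.351 to 32.6 ± 4.39 CPM. The aryl hydrocarbon receptor targets moved by a median log2 fold change of 2.55, and 7 rose and 0 fell of 9 (camera adjusted p = 5.7e-08). HAS1, a hyaluronan synthase, rose from 0.330 ± 0.0488 to 15.8 ± 1.02 CPM and OVOL1 from 3.30 ± 0.366 to 73.6 ± 9.24 CPM. Of the 8 tested metallothioneins, 7 rose and 0 fell, with a median log2 fold change of 1.54 (camera adjusted p = 4.5e-06, and adjusted p = 0.096 with an estimated correlation). MT1G rose from 1.90 ± 0.424 to 12.5 ± 2.18 CPM, with reads that can be shared between metallothionein genes. Among 24 NRF2 oxidative stress genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone), and the median log2 fold change was 0.55 (camera adjusted p = 1.3e-08, and adjusted p = 0.10 with an estimated correlation). HMOX1 rose from 6.29 ± 0.427 to 48.2 ± 4.51 CPM and OSGIN1 from 4.79 ± 1.16 to 20.9 ± 1.72 CPM. 7 neutrophil chemokines were tested, and 4 rose and 0 fell (4 and 1 adjusted over the list alone) (median log2 fold change 0.91, camera adjusted p = 0.0031, and adjusted p = 0.070 with an estimated correlation). CXCL8 rose from 6.69 ± 0.982 to 17.6 ± 2.42 CPM and CCL20 from 0.543 ± 0.136 to 3.33 ± 0.575 CPM. Cytokines had 29 tested members, of which 15 rose and 2 fell (median log2 fold change 0.86, camera adjusted p = 1.7e-06, and adjusted p = 0.070 with an estimated correlation). IL36G rose from 3.15 ± 0.837 to 66.5 ± 4.63 CPM and LIF from 4.95 ± 0.201 to 33.9 ± 8.74 CPM. For NF-kB feedback and target genes, 19 rose and 0 fell (20 and 1 adjusted over the list alone) out of 26 (median log2 fold change 1.10, camera adjusted p = 3.2e-10). TNFAIP2 rose from 3.02 ± 0.812 to 20.1 ± 2.17 CPM. The immediate early and AP-1 genes moved by a median log2 fold change of 0.73, and 16 rose and 1 fell (17 and 1 adjusted over the list alone) of 24 (camera adjusted p = 4.6e-09, and adjusted p = 0.10 with an estimated correlation). ATF3 rose from 7.77 ± 1.34 to 83.5 ± 4.98 CPM. Of the 22 tested matrix proteases and inhibitors, 12 rose and 2 fell (14 and 2 adjusted over the list alone), with a median log2 fold change of 0.55 (camera adjusted p = 8.4e-06, and adjusted p = 0.12 with an estimated correlation). PLAUR rose from 21.8 ± 3.54 to 407 ± 41.8 CPM.

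Genes that fell with S. epidermidis included DKK1, an inhibitor of Wnt signalling, from 214 ± 15.5 to 22.4 ± 2.15 CPM, the adhesion protein gene FLRT3 from 82.9 ± 20.2 to 14.2 ± 4.35 CPM and EPHA4 from 21.1 ± 1.54 to 4.62 ± 0.881 CPM (adjusted p at most 2.8e-05). Among 25 type I interferon response genes, 1 rose and 11 fell (1 and 14 adjusted over the list alone), and the median log2 fold change was -0.65 (camera adjusted p = 3.7e-04, and adjusted p = 0.28 with an estimated correlation). IFIT1 fell from 153 ± 14.5 to 51.3 ± 7.79 CPM. 16 ERK feedback phosphatases and sprouty genes were tested, and 3 rose and 7 fell (3 and 9 adjusted over the list alone) (median log2 fold change -0.42, camera adjusted p = 0.025, and adjusted p = 0.40 with an estimated correlation, with 0.059 with GC offsets and 0.11 without S. epidermidis replicate 1 and 0.052 without S. epidermidis replicate 2 and 0.067 without media replicate 1). DUSP6 fell from 281 ± 18.4 to 90.6 ± 19.8 CPM and DUSP4 from 145 ± 0.264 to 55.9 ± 11.3 CPM. Keratinocyte differentiation genes had 31 tested members, of which 11 rose and 2 fell (14 and 2 adjusted over the list alone) (median log2 fold change 0.36, camera adjusted p = 1.7e-05, and adjusted p = 0.28 with an estimated correlation). ZNF750 rose from 2.605 ± 0.373 to 32.0 ± 0.687 CPM and TGM1, a transglutaminase of the cornified envelope, from 8.44 ± 0.729 to 33.7 ± 6.16 CPM. For genes of the integrated stress response and amino acid deprivation, 9 rose and 2 fell (17 and 2 adjusted over the list alone) out of 27 (median log2 fold change 0.36, camera adjusted p = 1.9e-04, and adjusted p = 0.32 with an estimated correlation). The genes of cholesterol synthesis and uptake moved by a median log2 fold change of 0.28, and 7 rose and 0 fell (9 and 0 adjusted over the list alone) of 23 (camera adjusted p = 7.7e-04, and adjusted p = 0.12 with an estimated correlation). INSIG1 rose from 112 ± 5.39 to 271 ± 8.85 CPM. Of the 25 tested mitotic cell cycle genes, 1 rose and 2 fell (1 and 1 adjusted over the list alone), with a median log2 fold change of -0.18 (camera adjusted p = 0.14). Against media, 3787 genes differed with S. epidermidis in edgeR's test, 2095 higher and 1692 lower, and 1344 by 2-fold or more (761 higher and 583 lower). For S. epidermidis, the calls were 1449 higher and 3007 lower with total-count scaling (median of all tested genes -0.18). Beside the 3787 calls, a GC covariate gave 7836 calls (3885 higher, 3951 lower) and a test against a fold change of 1.5 gave 907. Without media replicate 3 the count was 2438, with only the 2 groups in the fit 1986 and with GC offsets 6026 (2925 higher, 3101 lower).

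**Figure D3:**
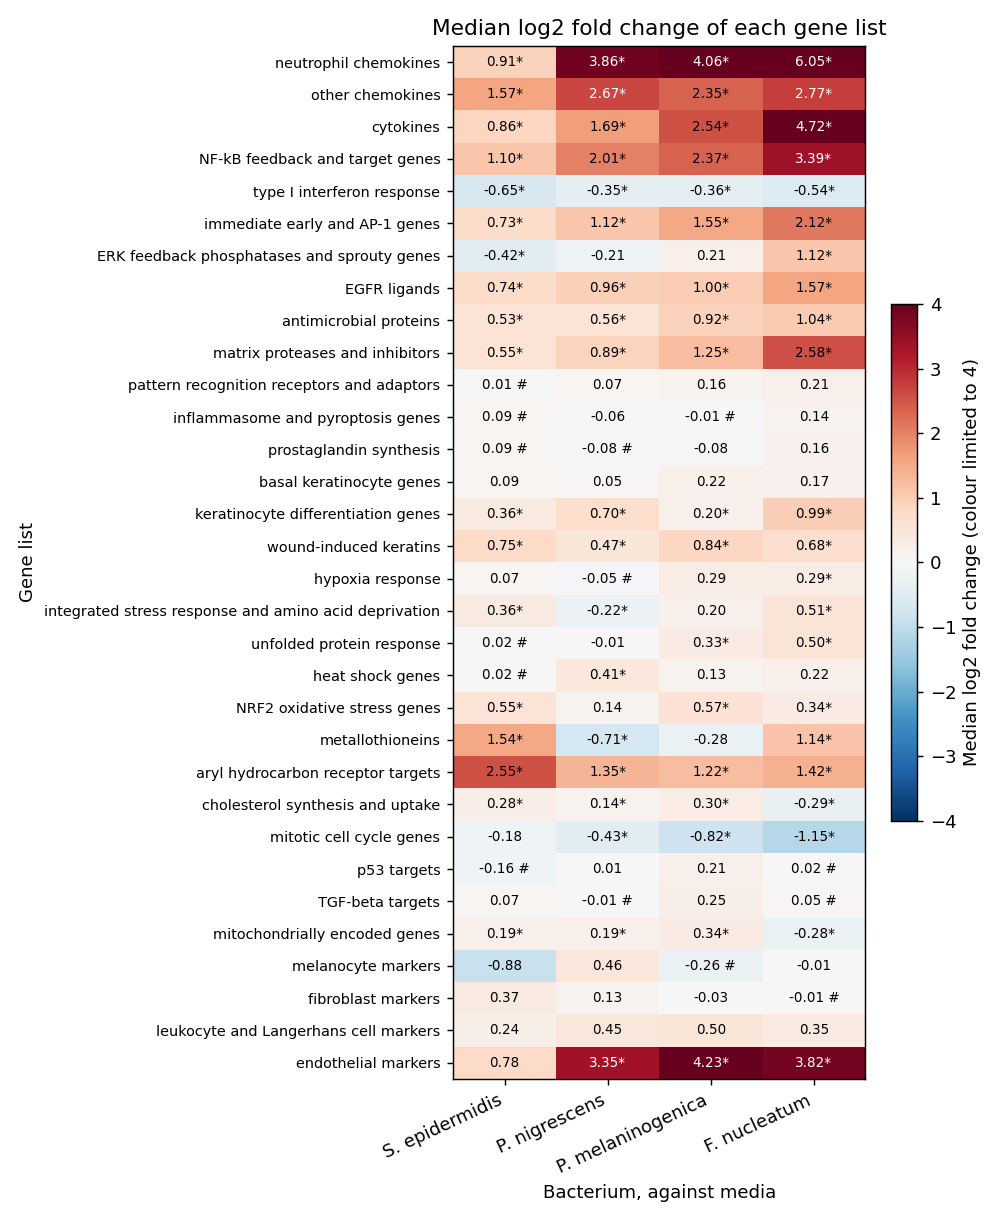
Median log2 fold change against media of each of the 32 gene lists (rows) with each bacterium (columns), as numbers on a colour scale limited to 4 on either side of 0. An asterisk marks an adjusted p under 0.05 in the camera test with its preset correlation, and a hash marks a median whose sign relative to the median of all genes changed with GC offsets or a GC covariate, which 14 of the medians did, 0 of them with an asterisk.

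Genes shared by the bacteria. Against media, 981 genes were higher and 506 lower with all 4 bacteria in edgeR's test, where independent lists of these sizes would share 12.2 and 6.48. In 20 simulations of unchanged groups that shared simulated media libraries, the highest number shared by all 4 comparisons was 0 in either direction. A single simulated comparison had at most 1 call, so this does not measure how far the shared libraries raise the overlap. CYP1A1, IL36G, OVOL1, GRHL3, PLAUR and ATF3 rose with each bacterium, and IFIT1, CCN2 and SPRY1 fell with each, with an adjusted p of at most 3.9e-04 in each comparison. The 4 comparisons share their media libraries, which are too few to split, so part of the excess may come from the shared controls. Across the 13313 genes above 1 CPM, the log2 fold changes against media had a Pearson correlation of 0.90 between F. nucleatum and P. melaninogenica, 0.84 between P. nigrescens and P. melaninogenica and 0.83 between P. nigrescens and F. nucleatum. With S. epidermidis the correlations were 0.74 for P. melaninogenica, 0.61 for F. nucleatum and 0.53 for P. nigrescens. Spearman correlations gave another order: 0.78, 0.57 and 0.64 for the pairs of anaerobes and 0.71, 0.53 and 0.23 with S. epidermidis. These have no GC correction and may follow GC content: only P. nigrescens had a mean GC slope below media. Unchanged groups simulated against the same controls gave a Pearson correlation of 0.48 for the first pair and 0.49 for the last. The covariance was 0.90 for the first pair and 0.27 for the last, against simulated values of 0.027 and 0.027, and genes are not independent replicates. Without media replicate 3, 335 genes were lower with all 4 bacteria, and total-count scaling gave 1353, GC offsets 1448, the fit without the 5 libraries that stood apart on the GC axis 1005 and the fits of only 2 groups 326. A GC covariate gave 1944 higher and 1844 lower, and a test against a fold change of 1.5 gave 382 and 66.

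The anaerobes against S. epidermidis. The only other bacterium was S. epidermidis, so anaerobic growth, Gram type and species cannot be told apart here. Higher with each of the 3 anaerobes than with S. epidermidis were 1207 genes and lower 906, where independent lists would share 70.0 and 45.4. Unchanged groups in 20 simulations shared 0 genes, with at most 2 calls in any 1 comparison. This does not measure what the shared S. epidermidis libraries add, which may be part of the excess. In the order P. nigrescens, F. nucleatum and P. melaninogenica, the log2 differences from S. epidermidis were among the largest in every anaerobe for NR4A3 by 5.62, 7.93 and 6.10, CXCL8 by 5.05, 8.09 and 4.90, CCL20 by 4.52, 8.05 and 5.95 and IL6 by 3.90, 7.35 and 3.97. The genes lower with all 3 were led by ALDH3A1, with -3.06, -4.07 and -2.496, followed by PHYHIP with -2.41, -2.83 and -2.00. CXCL8 stood at 584 ± 49.5 against 17.6 ± 2.42 CPM for P. nigrescens and S. epidermidis (adjusted p = 5.3e-10), at 4779 ± 140.0 CPM with F. nucleatum and at 526 ± 64.8 CPM with P. melaninogenica (adjusted p = 1.8e-12 and 1.4e-10). ALDH3A1 and PHYHIP were higher with S. epidermidis than in media, by 3.72 and 2.96 (log2). Part of the lower set may thus reflect such a rise. ALDH3A1 stood at 1.94 ± 0.213 against 32.6 ± 4.39 CPM with F. nucleatum and S. epidermidis, at 3.90 ± 0.203 CPM with P. nigrescens and 5.79 ± 1.64 CPM with P. melaninogenica, and at 2.46 ± 0.351 CPM in media. Total-count scaling gave 1656 genes lower with all 3, GC offsets 2275 and the fit without the 5 libraries that stood apart on the GC axis 1363. The counts higher and lower were 2481 and 2267 with a GC covariate, 457 and 150 in a test against a fold change of 1.5, and 625 and 417 in fits of only 2 groups.

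P. nigrescens against S. epidermidis. Among 7 neutrophil chemokines, 6 were higher and 0 lower, and the median log2 fold change was 3.15 (camera adjusted p = 1.0e-07). 26 NF-kB feedback and target genes were tested, and 20 were higher and 0 lower (23 and 0 adjusted over the list alone) (median log2 fold change 1.01, camera adjusted p = 9.6e-12). TNFAIP2 stood at 295 ± 23.1 against 20.1 ± 2.17 CPM, and IL16 at 18.5 ± 2.68 against 0.340 ± 0.0959 CPM. Metallothioneins had 8 tested members, of which 0 were higher and 7 lower (0 and 8 adjusted over the list alone) (median log2 fold change -2.48, camera adjusted p = 2.8e-06, and adjusted p = 0.11 with an estimated correlation). MT1G stood at 1.20 ± 0.472 against 12.5 ± 2.18 CPM and MT1X at 1.77 ± 0.253 against 11.2 ± 2.16 CPM. For genes of the integrated stress response and amino acid deprivation, 0 were higher and 18 lower (1 and 18 adjusted over the list alone) out of 27 (median log2 fold change -0.59, camera adjusted p = 9.0e-06, and adjusted p = 0.35 with an estimated correlation). DDIT3 stood at 7.21 ± 1.14 against 31.5 ± 0.456 CPM (adjusted p at most 3.0e-06 for these 5 genes). The NRF2 oxidative stress genes moved by a median log2 fold change of -0.40, and 2 were higher and 16 lower of 24 (camera adjusted p = 7.2e-04, and adjusted p = 0.35 with an estimated correlation). HMOX1 stood at 13.6 ± 1.43 against 48.2 ± 4.51 CPM. In edgeR's test 7048 genes differed, 3578 higher and 3470 lower with P. nigrescens, and 2612 by 2-fold or more. Between P. nigrescens and S. epidermidis, the calls were 3463 higher and 5689 lower with GC offsets (median of all tested genes -0.12). Beside the 7048 calls, a test against a fold change of 1.5 gave 1898. Without P. nigrescens replicate 1 the count was 4596, and with only the 2 groups in the fit 4675.

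F. nucleatum against S. epidermidis. Of the 29 tested cytokines, 23 were higher and 0 lower (26 and 0 adjusted over the list alone), with a median log2 fold change of 3.37 (camera adjusted p = 6.3e-19). CSF3 stood at 530.4 ± 72.9 against 2.53 ± 1.36 CPM and IL23A, a subunit of interleukin 23, at 359.7 ± 28.6 against 3.95 ± 0.590 CPM. Among 26 NF-kB feedback and target genes, 25 were higher and 0 lower (26 and 0 adjusted over the list alone), and the median log2 fold change was 2.47 (camera adjusted p = 6.3e-23). 22 matrix proteases and inhibitors were tested, and 17 were higher and 0 lower (18 and 0 adjusted over the list alone) (median log2 fold change 1.68, camera adjusted p = 8.5e-12). MMP13 stood at 43.6 ± 7.61 against 0.653 ± 0.243 CPM. Unfolded protein response genes had 23 tested members, of which 15 were higher and 0 lower (19 and 0 adjusted over the list alone) (median log2 fold change 0.59, camera adjusted p = 2.0e-06, and adjusted p = 0.11 with an estimated correlation). HERPUD1 stood at 1172 ± 103 against 258 ± 5.85 CPM. For genes of cholesterol synthesis and uptake, 0 were higher and 16 lower out of 23 (median log2 fold change -0.71, camera adjusted p = 2.1e-08). HMGCS1 stood at 166 ± 26.5 against 799.5 ± 249 CPM and INSIG1 at 108 ± 9.35 against 271 ± 8.85 CPM. The mitotic cell cycle genes moved by a median log2 fold change of -0.84, and 0 were higher and 14 lower (0 and 15 adjusted over the list alone) of 25 (camera adjusted p = 2.1e-08). AURKA stood at 11.5 ± 0.838 against 39.2 ± 2.52 CPM (adjusted p at most 4.7e-06 for these 7 genes). Of the 13 tested mitochondrially encoded genes, 0 were higher and 13 lower, with a median log2 fold change of -0.42 (camera adjusted p = 1.7e-07, and adjusted p = 0.15 with an estimated correlation). The test called 6252 genes, 3450 higher and 2802 lower with F. nucleatum, 2744 by 2-fold or more. Between F. nucleatum and S. epidermidis, the calls were 2656 higher and 5346 lower with total-count scaling (median of all tested genes -0.19) and 3502 higher and 6101 lower with GC offsets (median of all tested genes -0.16). Beside the 6252 calls, a GC covariate gave 10658 calls and a test against a fold change of 1.5 gave 2500.

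P. melaninogenica against S. epidermidis. Among 26 NF-kB feedback and target genes, 24 were higher and 0 lower (26 and 0 adjusted over the list alone), and the median log2 fold change was 1.44 (camera adjusted p = 1.8e-27). ICAM1 stood at 452 ± 68.1 against 31.4 ± 5.93 CPM. 29 cytokines were tested, and 19 were higher and 0 lower (20 and 1 adjusted over the list alone) (median log2 fold change 1.751, camera adjusted p = 4.0e-17). Metallothioneins had 8 tested members, of which 0 were higher and 7 lower (median log2 fold change -1.71, camera adjusted p = 1.6e-07, and adjusted p = 0.060 with an estimated correlation). MT1G stood at 1.22 ± 0.432 against 12.5 ± 2.18 CPM. For mitotic cell cycle genes, 0 were higher and 11 lower out of 25 (median log2 fold change -0.54, camera adjusted p = 5.7e-07). The genes of cholesterol synthesis and uptake had a median log2 fold change of -0.021, or 0.0014 with a GC covariate, and 0 were higher and 0 lower of 23 (camera adjusted p = 0.93). The test called 3398 genes, 1864 higher and 1534 lower with P. melaninogenica, 1348 by 2-fold or more. Between P. melaninogenica and S. epidermidis, the calls were 1514 higher and 2578 lower with total-count scaling (median of all tested genes -0.11) and 2448 higher and 3241 lower with GC offsets (median of all tested genes -0.051). Beside the 3398 calls, a GC covariate gave 8102 calls and a test against a fold change of 1.5 gave 990. With only the 2 groups in the fit the count was 1488, and without the 5 libraries that stood apart on the GC axis it was 5904 (2910 higher, 2994 lower).

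Differences among the anaerobes. F. nucleatum gave higher levels of inflammatory genes than P. nigrescens. IL23A stood at 359.7 ± 28.6 against 8.64 ± 2.07 CPM, IL20, a cytokine acting on keratinocytes, at 315 ± 26.8 against 7.62 ± 0.191 CPM and CXCL8 at 4779 ± 140.0 against 584 ± 49.5 CPM (adjusted p at most 3.3e-09). Of the 29 tested cytokines, 21 were higher and 2 lower (23 and 3 adjusted over the list alone), with a median log2 fold change of 1.89 (camera adjusted p = 4.4e-17). Among 27 genes of the integrated stress response and amino acid deprivation, 20 were higher and 0 lower (22 and 0 adjusted over the list alone), and the median log2 fold change was 0.63 (camera adjusted p = 1.1e-10, and adjusted p = 0.096 with an estimated correlation). DDIT3 stood at 69.1 ± 8.70 against 7.21 ± 1.14 CPM. 8 metallothioneins were tested, and 8 were higher and 0 lower (median log2 fold change 2.14, camera adjusted p = 3.2e-07). Genes of cholesterol synthesis and uptake had 23 tested members, of which 0 were higher and 13 lower (0 and 14 adjusted over the list alone) (median log2 fold change -0.50, camera adjusted p = 1.6e-09). HMGCS1 stood at 166 ± 26.5 against 895 ± 71.8 CPM. IL16 went the other way, with 3.56 ± 0.353 against 18.5 ± 2.68 CPM. The test called 4300 genes, 2539 higher and 1761 lower with F. nucleatum. Between F. nucleatum and P. nigrescens, the calls were 1917 higher and 3667 lower with total-count scaling (median of all tested genes -0.19) and 2761 higher and 3337 lower with GC offsets (median of all tested genes -0.049). Beside the 4300 calls, a GC covariate gave 7625 calls and a test against a fold change of 1.5 gave 1391. Without 4 of the libraries that stood apart on the GC axis the count was 9070, and 10505 without all 5.

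Against P. melaninogenica, F. nucleatum had IL20 at 315 ± 26.8 against 15.2 ± 1.07 CPM, IL6 at 1201 ± 138 against 116 ± 11.7 CPM and CXCL8 at 4779 ± 140.0 against 526 ± 64.8 CPM. For EGFR ligands, 5 were higher and 0 lower (6 and 0 adjusted over the list alone) out of 8 (median log2 fold change 0.99, camera adjusted p = 1.2e-05). The genes of cholesterol synthesis and uptake moved by a median log2 fold change of -0.74, and 0 were higher and 16 lower (0 and 17 adjusted over the list alone) of 23 (camera adjusted p = 6.6e-14). Of the 13 tested mitochondrially encoded genes, 0 were higher and 13 lower, with a median log2 fold change of -0.63 (camera adjusted p = 1.0e-14). ZNF750 stood at 7.82 ± 1.19 against 37.1 ± 3.46 CPM and HJURP at 3.52 ± 0.310 against 25.5 ± 2.01 CPM (adjusted p at most 7.8e-08 for these 5 genes). Called genes numbered 3498, 2148 higher and 1350 lower with F. nucleatum. Between F. nucleatum and P. melaninogenica, the calls were 1882 higher and 2463 lower with total-count scaling (median of all tested genes -0.043) and 2571 higher and 3742 lower with GC offsets (median of all tested genes -0.078). Beside the 3498 calls, a GC covariate gave 8531 calls and a test against a fold change of 1.5 gave 860. Without the 5 libraries that stood apart on the GC axis the count was 6252.

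P. nigrescens and P. melaninogenica, the 2 Prevotella species, were compared directly. IL16 stood at 18.5 ± 2.68 against 3.27 ± 0.460 CPM with P. nigrescens and P. melaninogenica, HERPUD1 at 113 ± 4.96 against 472 ± 40.1 CPM and CHAC1 at 10.9 ± 1.46 against 48.2 ± 12.4 CPM (adjusted p at most 7.7e-05). Among 26 NF-kB feedback and target genes, 0 were higher and 12 lower (1 and 13 adjusted over the list alone), and the median log2 fold change was -0.43 (camera adjusted p = 4.2e-06). ICAM1 stood at 165 ± 13.7 against 452 ± 68.1 CPM. 23 unfolded protein response genes were tested, and 0 were higher and 11 lower (0 and 15 adjusted over the list alone) (median log2 fold change -0.44, camera adjusted p = 4.0e-05, and adjusted p = 0.26 with an estimated correlation). NRF2 oxidative stress genes had 24 tested members, of which 1 was higher and 8 lower (1 and 13 adjusted over the list alone) (median log2 fold change -0.39, camera adjusted p = 3.2e-05, and adjusted p = 0.29 with an estimated correlation). The test called 2828 genes, 1288 higher and 1540 lower with P. nigrescens, while of the 876 that differed by 2-fold or more 621 were higher and 255 lower. Between the Prevotella species, the calls were 1802 higher and 1157 lower with total-count scaling (median of all tested genes 0.12). Beside the 2828 calls, a GC covariate gave 4377 calls and a test against a fold change of 1.5 gave 365 (208 higher, 157 lower). The count was 1208, 1280 and 1314 without P. nigrescens replicate 1, P. nigrescens replicate 2 and P. melaninogenica replicate 1, 1295 with only the 2 groups in the fit, and 6298 (3369 higher, 2929 lower) without 4 of the libraries that stood apart on the GC axis and 8218 (4246 higher, 3972 lower) without all 5, and 4661 (1821 higher, 2840 lower) with GC offsets.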

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

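The GC corrections and the fits without 4 and without 5 libraries were chosen after seeing the data. The named genes kept their direction and their side of the threshold under each alternative, single libraries left out included, with these exceptions. In the test against a fold change of 1.5, AURKA and PTGER4 with P. nigrescens, HERPUD1 with P. melaninogenica, and HSPB8 and PTGS2 with S. epidermidis, all against media, were not called. PTGS2 with S. epidermidis was also not called with total-count scaling, with only the 2 groups in the fit (adjusted p = 0.065) and without S. epidermidis replicate 1, media replicate 1 or media replicate 2. Counts of called genes are given in the order P. nigrescens, F. nucleatum, P. melaninogenica and S. epidermidis against media, the first 3 against S. epidermidis, F. nucleatum against P. nigrescens and P. melaninogenica, and P. nigrescens against P. melaninogenica. The reported counts were 5690, 7058, 5656, 3787, 7048, 6252, 3398, 4300, 3498 and 2828. Against a fold change of 1.5 they were 2122, 3178, 1842, 907, 1898, 2500, 990, 1391, 860 and 365, as a stricter hypothesis gives, with 382 genes higher and 66 lower with all 4 bacteria and 457 higher and 150 lower with all 3 anaerobes than with S. epidermidis. A GC covariate gave 10376, 11237, 9813 and 7836 against media, 10658 and 8102 for F. nucleatum and P. melaninogenica against S. epidermidis, 7625, 8531 and 4377 between anaerobes, 1944 and 1844 with all 4 bacteria, and 2481 and 2267 with all 3 anaerobes. GC offsets gave 6026 for S. epidermidis against media, 9603 and 5689 for F. nucleatum and P. melaninogenica against S. epidermidis, 6313 and 4661 for F. nucleatum and P. nigrescens against P. melaninogenica, 1448 lower with all 4 bacteria and 2275 lower with all 3 anaerobes. Total-count scaling gave 1353 lower with all 4 bacteria and 1656 lower with all 3 anaerobes, where the median of all tested genes lay at -0.17, -0.38, -0.32 and -0.18 (log2) against media. The cause of the GC differences was not tested. Without 4 of the libraries that stood apart on the GC axis, which leaves 2 in 4 of the groups, P. nigrescens gave 9816 against media and 9070 and 6298 against F. nucleatum and P. melaninogenica. Without F. nucleatum replicate 3 as well, which leaves 2 in each group, the counts were 10983 for P. nigrescens against media, 5904 for P. melaninogenica against S. epidermidis, 10505, 6252 and 8218 between anaerobes, 1005 lower with all 4 bacteria and 1363 lower with all 3 anaerobes. The cause of these higher counts was not tested. With only the 2 groups in the fit, and so fewer samples, the counts were 1986 for S. epidermidis against media, 4675 and 1488 for P. nigrescens and P. melaninogenica against S. epidermidis, 1295 between the Prevotella species, 326 lower with all 4 bacteria, and 625 and 417 with all 3 anaerobes.

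With 1 library left out in turn, the counts ranged over 4446 to 5588, 5986 to 6443, 4274 to 5236, 2438 to 3625, 4596 to 8011, 5012 to 6098, 2462 to 3456, 3072 to 4365, 2574 to 2953 and 1208 to 3849. The range was 794 to 1024 for genes higher and 335 to 541 for genes lower with all 4 bacteria, and 968 to 1314 and 627 to 1037 with all 3 anaerobes. Of these counts, 6 moved by over 1.5 times. Without media replicate 3 they were 2438 for S. epidermidis against media and 335 lower with all 4. Without P. nigrescens replicate 1 the count between P. nigrescens and S. epidermidis was 4596. Between the Prevotella species it was 1208 and 1280 without P. nigrescens replicates 1 and 2 and 1314 without P. melaninogenica replicate 1. Lists called against media numbered 19, 22, 18 and 18, and 5, 9, 8 and 2 with an estimated correlation, with 16 to 19, 22 throughout, 17 to 19 and 17 to 18 when 1 library was left out. Of single list results against media, 53 lost the call with an estimated correlation, 15 lost and 7 gained it with 1 library left out, 3 lost it with GC offsets, 1 gained it with DESeq2 size factors, and 3 lost and 25 gained it with fry, which asks whether a list moves one way and not whether it differs from other genes. Across the 4 bacteria against media, list medians relative to the median of all genes changed sign 9 times with GC offsets and 13 times with the GC covariate, 0 times in a called list. DESeq2, DESeq2 size factors and no low-count filter left the counts of calls within 1.5 times of the reported ones. EdgeR called 12, 6, 14 and 10 of 50 genes simulated at 1.5-fold for the 4 bacteria against media. Few genes changed there, so this may not hold for the data.

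Libraries with the same replicate number did not all deviate together: the correlations of their deviations ran from -0.65 to 0.62, and 2 of 15 libraries correlated best with their own number. With the replicate number as a replicate block, 1713 genes were called between P. nigrescens and P. melaninogenica, against 2828 without it. Every other count of calls was within 1.5 times of the one without it, such as 4944 between P. nigrescens and media. No call of a list against media changed.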

Other observations

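Of the tests on these patterns, 1 was chosen only after the result was seen, that of the cholesterol genes against the other genes. Further genes moved with 3 or all of the bacteria, with log2 fold changes against media given for P. nigrescens, F. nucleatum, P. melaninogenica and S. epidermidis in this order (edgeR). HSPB8 and CRYAB, which encode small heat shock proteins, rose by 2.03 ± 0.16, 3.48 ± 0.16, 2.53 ± 0.16 and 0.84 ± 0.16 and by 1.49 ± 0.12, 2.82 ± 0.12, 1.71 ± 0.12 and 1.68 ± 0.12 (adjusted p at most 0.0020). With P. nigrescens, among 20 heat shock genes, 7 rose and 1 fell, and the median log2 fold change was 0.41 (camera adjusted p = 0.016, and adjusted p = 0.052 with an estimated correlation). PTGS2, the inducible cyclooxygenase, rose by 1.85 ± 0.21, 3.14 ± 0.22, 1.40 ± 0.21 and 0.79 ± 0.20 (adjusted p at most 0.014). Its call with S. epidermidis was lost when any 1 of 3 libraries was left out: the log2 fold change was 0.60 without S. epidermidis replicate 1 (adjusted p = 0.054) and 0.70 and 0.74 without media replicates 1 and 2 (adjusted p = 0.055 and 0.055), and 0.63 with total-count scaling (adjusted p = 0.062). PTGER4, a receptor of prostaglandin E2, fell, with values of -0.76 ± 0.11, -1.30 ± 0.11 and -1.83 ± 0.11 with P. nigrescens, P. melaninogenica and S. epidermidis (adjusted p at most 1.2e-04). The growth arrest genes BTG2 and GADD45A rose by 2.25 ± 0.12, 2.45 ± 0.12, 2.26 ± 0.12 and 1.74 ± 0.11 and 1.66 ± 0.08, 1.94 ± 0.08, 1.58 ± 0.08 and 1.43 ± 0.08 (adjusted p at most 1.5e-07), while the p53 targets as a list were not called with any of the 4 (camera adjusted p = 0.17 or more). With S. epidermidis, 9 other chemokines were tested, and 5 rose and 2 fell (6 and 2 adjusted over the list alone) (median log2 fold change 1.57, camera adjusted p = 0.0055, and adjusted p = 0.070 with an estimated correlation).

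More genes were called between P. nigrescens and S. epidermidis than between P. melaninogenica and S. epidermidis, by a ratio of 2.07. The ratio ran from 1.44 without P. nigrescens replicate 1 to 2.86 without S. epidermidis replicate 1. As tests of GC content bias, the ratio was 1.61 with GC offsets and 1.04 with a GC covariate, and leaving out 4 libraries far from their groups on the GC axis gave 2.05, with 10412 and 5904 calls when F. nucleatum replicate 3 was left out too. The 2 GC corrections gave different values, and those with GC offsets and without 4 libraries lie within the range over single libraries, so GC content bias, libraries far from their group and a difference between the bacteria, which was not tested by itself, cannot be told apart.

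Mitotic cell cycle genes were lower with F. nucleatum than in media, with a median log2 fold change of -1.15 and no nearer 0 than -0.96 with 1 library left out. The median was -0.97 under the GC correction that moved it nearest to 0, which argues against GC content as the whole cause. Relative to the median of all genes it was -1.12 with total-count scaling. Scaling shifts all genes alike and leaves this difference as it is, so the value does not test scaling. A candidate explanation is a lower share of dividing cells, for which genes of S phase would fall too. Their median was -0.50, with 6 of 9 lower and 0 higher, and relative to the median of all genes -0.48, with -0.57, -0.59 and -0.48 with GC offsets, a GC covariate and total-count scaling, on both sides of the bound of -0.5 set beforehand. Single libraries move the median by 0.088 either way, so this explanation stays open.

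Genes of cholesterol synthesis and uptake were lower with F. nucleatum than with P. nigrescens, with a median log2 difference of -0.50 (-0.57 to -0.43 with 1 library left out). It was -0.62 or further from 0 with GC corrections, and -0.57 or further relative to the median of all genes, which argues against GC content as the whole cause. With total-count scaling the list lay at -0.50 from the median of all genes, near the bound set beforehand. Scaling alters neither this nor the camera test against other genes (adjusted p = 0.013, estimated correlation), so neither tests it. A response to the bacterium stays open as a hypothesis and was not tested further.

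Each of the 10 comparisons allows 10 splits of its 6 libraries, 1 of them the real one, which is too few for a share under 0.05. The real groupings gave the reported counts of calls, and the highest of the other splits gave 0 in each (edgeR, adjusted p). At an unadjusted p under 0.05 the other splits gave 159 to 3316, 118 to 761, 152 to 2610, 176 to 3086, 155 to 4836, 160 to 2487, 177 to 5749, 171 to 3153, 191 to 2554 and 189 to 4242 genes, against 7391, 8335, 7638, 6275, 9118, 7791, 5270, 6497, 5476 and 6928. For P. melaninogenica and S. epidermidis the split of P. melaninogenica replicate 1 with S. epidermidis replicates 2 and 3 gave 5749 genes at an unadjusted p under 0.05, above the real 5270, which points to a structure of the samples: these 3 had the 3 highest slopes of log2 CPM on GC content of the 6, at 0.38, 0.05 and 0.43 per 10 percentage points, and the others -0.011, -0.061 and -0.089.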
